A study of Mus musculus with 65 samples.

How the data were processed

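RNA was sequenced from FACS-sorted cells of mouse femur and tibia after enzymatic digestion and antibody staining, with libraries made by a SMARTer low-input kit with Nextera, per the labels' protocols. Per the submitters' processing notes the tools were bcl2fastq 2.18, TopHat2 2.0.13 and Cufflinks 2.2.1, with the genome build mm10. The deposited values are FPKM per gene, that is, fragments scaled by transcript length and by mapped fragments, in 3 sets: HSPC groups, niche populations in homeostasis, and N-cadherin reporter cells after 5FU. Whether the tables were normalized jointly is not given in the sources used here, so no gene was tested across tables except in an interaction, where a constant offset of a gene cancels. Sheets of group means made by the authors were not used. The day of 5FU for the niche cells is not given in the sources used here, and 1 label of 5FuReserve writes CD49- where the others write CD49b-.

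The tables listed 44500, 44381 and 47530 genes for HSPCs, niche cells and niche cells after 5FU, and 15, 28 and 4 genes with a missing value were left out. The values after 5FU came with gene IDs and no names. Names came from the other tables and, for 3092 of 3149 IDs those tables lack, from a reference list of gene names. Positions are from the GENCODE mouse release M21 annotation of mm10. FPKM keeps no absolute depth. Ratios of low values in pairs of libraries, where equal read numbers pile up, gave relative depths per library. These depths matched the ratio of a pair within 0.1 on the log2 scale in 65.4% of HSPC, 84.6% of niche and 80.0% of 5FU niche pairs. FPKM is uncertain for very short genes, such as mitochondrial tRNAs and joining segments. It is also uncertain for near-identical copies whose reads can be shared, such as globin, Bglap, Hspa1a and Hspa1b, Ifitm, Gbp and immunoglobulin genes.

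Each comparison was fitted with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) on log2(FPKM + 1) with a mean-variance trend, for genes with an FPKM of at least 1 in at least 3 libraries of the fitted table. All groups of a table shared the estimate of the spread. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and genes were called at an adjusted p under 0.05. There were 10 such comparisons and 28 gene lists fixed before the data were examined. Those with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with an estimated correlation and with fry, which asks whether members move one way on balance. Lists share some members, such as Btg2. Ligand levels over the 10 niche populations were tested with limma's moderated F test.

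The genes named in the text came from a rule fixed before the data were examined. For each comparison it takes the transcripts of the sorting markers, for each list called by camera or with 3 called members the up to 4 members with the smallest p, and the 5 genes with the largest rise and fall among called genes. The latter need a mean of at least 5 FPKM in the higher group and no overlap between the libraries compared, and unnamed gene models are left out. The text prints part of these genes, and levels of other list members or of sex-linked genes were chosen after their values were seen, as said there.

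Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a filter on a mean FPKM of at least 5, median-of-ratios scaling, only the compared groups in the fit, the replicate number as a block, and leaving out each library in turn. A fit of protein-coding genes alone was added after the data were seen. Splits of the libraries into other groups of the same sizes were counted, at most 100 per comparison. The fit was tested on simulated data with each gene's mean and residual spread, no group effect, and 100 genes changed per fold size. For Primed against Reserve (16171 genes) it recovered 60% of genes changed by a log2 fold of 1 and 84% of those changed by 2, and 6.49% of its calls were false. For the interaction (13316 genes) these shares were 27% and 70%, with 1.02% of its calls false. Calls were 6.12% false for 5FuReserve against Reserve (16171 genes) and 5.62% for Ncad_marrow against Lepr (18972 genes).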

Results

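Gene expression was measured by RNA sequencing in 65 libraries of FACS-sorted mouse cells from femur and tibia, which fall into 17 groups of 3 to 6 libraries. The first set held hematopoietic stem and progenitor cells (HSPCs) of the LSK gate (lineage-negative, Sca-1 and c-Kit positive). Reserve stem cells were Flk2-, CD34- and CD49b- (n = 4), and primed stem cells (Primed) were CD49b+ in the same gate (n = 3). Short-term stem cells (ST) were Flk2- CD34+ (n = 3) and multipotent progenitors (MPP) Flk2+ CD34+ (n = 4). A further group, 5FuReserve, was taken with the reserve gate on day 3 after 5-fluorouracil (5FU), a drug that kills dividing cells (n = 3). The second set held niche cells in homeostasis: reporter cells negative for CD45, Ter119 and CD31 from the N-cadherin (Tomato) reporter, from bone (Ncad_bone) and from marrow (Ncad_marrow), stromal cells marked by Col2.3-GFP, Cxcl12-DsRed, Nestin-GFP or Ng2-RFP, Pecam-GFP cells, F4/80+ macrophages (Mac) and Pf4-Cre-marked cells (MK), each with n = 4, and Lepr+ cells with n = 6. The third set held N-cadherin reporter cells of bone and of marrow after 5FU (n = 3 each).

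The values were FPKM, so absolute sequencing depth was unknown. Between 11670 and 14258 genes per library had an FPKM of at least 1. The spacing of the lowest values gave relative depths that differed at most 4.14-fold among HSPC libraries, 6.39-fold among niche libraries and 2.55-fold among the niche libraries after 5FU. The 10 genes with the highest FPKM, mostly very short ones, held 32.9% to 86.9% of a library's FPKM. Fold changes are on the log2(FPKM + 1) scale with their standard error, which understates changes of low genes. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

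Sorting marker transcripts were read first. Flt3, which encodes Flk2, was at 89.3 ± 9.27 FPKM (SD, n = 4) in MPP and 13.2 ± 3.49 FPKM (SD, n = 4) in Reserve, and Cd34 was at 285 ± 23.3 FPKM (SD, n = 4) and 78.1 ± 20.3 FPKM (SD, n = 4). Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722) was at 109 ± 2.56 FPKM (SD, n = 4) in Reserve. Itga2, which encodes CD49b, was below 1 FPKM on average in each HSPC group, at 0.663 ± 0.161 FPKM (SD, n = 3) in Primed and 0.198 ± 0.340 FPKM (SD, n = 4) in Reserve, too low to be tested. Positions are on mm10 (GENCODE M21). In the niche set, Col1a1 was at 904 ± 124 FPKM (SD, n = 4) in Col2.3_GFP cells and 2277 ± 263 FPKM (SD, n = 4) in Ng2_RFP cells, Pecam1 at 87.1 ± 9.64 FPKM (SD, n = 4) in Pecam_GFP cells and Cspg4, which encodes Ng2, at 13.8 ± 2.86 FPKM (SD, n = 4) in Ng2_RFP cells. Pf4 was at 19011 ± 14282 FPKM (SD, n = 4) in MK. Adgre1, which encodes F4/80, was at 19.1 ± 3.83 FPKM (SD, n = 4) in Mac and 20.9 ± 3.54 FPKM (SD, n = 4) in MK. Cdh2 (ENSMUSG00000024304, chromosome 18, 16588877 to 16809246), which encodes N-cadherin, was at 41.1 ± 3.42 FPKM (SD, n = 4) in Ncad_bone and 35.4 ± 1.51 FPKM (SD, n = 4) in Ncad_marrow, against 58.1 ± 5.75 FPKM (SD, n = 6) in Lepr, 56.1 ± 2.88 FPKM (SD, n = 4) in Ng2_RFP and 19.5 ± 4.36 FPKM (SD, n = 4) in Col2.3_GFP cells. Lepr (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352) was at 812 ± 137 FPKM (SD, n = 6) in Lepr+ cells and 1162 ± 243 FPKM (SD, n = 4) in Ncad_bone. Nes was at 0.390 ± 0.124 FPKM (SD, n = 4) in Nestin_GFP cells and 1.40 ± 0.483 FPKM (SD, n = 4) in Pecam_GFP cells.

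Primed stem cells were set against reserve stem cells first. Mllt3 (ENSMUSG00000028496, chromosome 4, 87769925 to 88033364), a transcriptional regulator of stem cell maintenance, was at 58.4 ± 14.3 FPKM (SD, n = 3) in Primed and 211 ± 12.0 FPKM (SD, n = 4) in Reserve (log2 fold change -1.86 ± 0.21). Vwf and Clu, listed as megakaryocyte genes, were lower in Primed, with log2 fold changes of -2.28 ± 0.25 and -3.45 ± 0.34, as was the growth factor gene Igf1 (-3.11 ± 0.33). Cd34 (1.35 ± 0.16) and Flt3 (1.12 ± 0.18) were higher, as was Prss34, a basophil and mast cell protease (7.08 ± 1.41, adjusted p = 0.012). Tm4sf1, a tetraspanin-like membrane protein, was lower (-3.33 ± 0.16, adjusted p = 4.3e-08). Kit was not called (adjusted p = 0.61).

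In the list of HSC stem cell genes, 0 of 34 members were higher and 13 lower (0 and 20 adjusted over the list alone, median log2 fold change -0.56, camera adjusted p = 5.8e-18, adjusted p = 5.7e-06 at an estimated correlation). These included Sult1a1 (-1.95 ± 0.12) and Pdzk1ip1 (-0.78 ± 0.11). For cell cycle genes, 10 of 37 members were higher and 0 lower (14 and 1 adjusted over the list alone, median log2 fold change 0.42, camera adjusted p = 2.0e-09, adjusted p = 0.11 at an estimated correlation). These included Uhrf1 (1.07 ± 0.13), a reader of replicating DNA, and Mcm5 (1.06 ± 0.15), a subunit of the replicative helicase. The megakaryocyte list had 0 higher and 4 lower of 20 (3 and 6 adjusted over the list alone, camera adjusted p = 0.043, adjusted p = 0.11 at an estimated correlation). Endothelial genes were lower too: 0 of 18 members were higher and 3 lower (0 and 4 adjusted over the list alone, median log2 fold change -0.27, camera adjusted p = 6.1e-04, adjusted p = 0.015 at an estimated correlation). Sox18 had a log2 fold change of -2.00 ± 0.18. Cldn5, a tight junction gene of endothelium, was at 5.31 ± 0.338 FPKM (SD, n = 4) in Reserve and listed at 0 in each Primed library. Neutrophil genes moved with these: 0 of 16 members were higher and 2 lower (0 and 7 adjusted over the list alone, median log2 fold change -1.65, camera adjusted p = 7.9e-05, adjusted p = 0.23 at an estimated correlation). Mpo, a neutrophil granule gene, stood at 212 FPKM in Primed replicate 1 and at 12.0 and 10.4 in replicates 2 and 3. Among erythroid genes, 0 of 15 members were higher and 1 lower (1 and 5 adjusted over the list alone, median log2 fold change -0.82, camera adjusted p = 0.011, adjusted p = 0.27 at an estimated correlation). HSC niche ligands, to which Igf1 belongs, had 0 higher and 6 lower of 38 (1 and 10 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.21 at an estimated correlation). Cxcl12 of that list, chosen after its values were seen, was called only without Reserve replicate 2 (adjusted p = 0.14, then 0.042), at 7.43, 1.49, 17.5 and 18.6 FPKM in Reserve and 0, 0.0550 and 5.42 FPKM in Primed.

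Across all genes, limma called 626 of 16171 genes, 260 higher and 366 lower, of which 97 and 212 had a log2 fold change of at least 1 in size. The count moved by over 1.5 times without Reserve replicate 3 (340), Reserve replicate 4 (333), Primed replicate 2 (215) or Primed replicate 3 (223). It was 342 of 9938 genes when the mean FPKM had to be at least 5, with the balance turned (197 higher and 145 lower). The call of Prss34 was lost without Primed replicate 2 (adjusted p = 0.058) or 3 (adjusted p = 0.057), and that of Flt3 with only Primed and Reserve fitted (adjusted p = 0.069).

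ST was set against Reserve next. Mki67, a marker of cycling cells, was at 24.1 ± 3.05 FPKM (SD, n = 3) in ST and 4.21 ± 0.285 FPKM (SD, n = 4) in Reserve (log2 fold change 2.26 ± 0.11), and Mllt3 at 33.0 ± 3.58 FPKM (SD, n = 3) in ST (-2.65 ± 0.21). Cd48 (2.53 ± 0.23), a surface marker gained by progenitors, and Dntt (2.22 ± 0.30), the lymphoid enzyme that adds bases to antigen receptor joints, were higher. Nkg7, a granule gene of cytotoxic lymphocytes, was also higher (2.95 ± 0.19, adjusted p = 2.2e-07). Smtnl1 (-3.72 ± 0.27) and Tm4sf1 (-3.42 ± 0.16) were among the genes with the lowest fold change in ST.

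Cell cycle genes were raised as a list: 34 of 37 members were higher and 0 lower (37 and 0 adjusted over the list alone, median log2 fold change 1.86, camera adjusted p = 8.5e-45, adjusted p = 5.2e-04 at an estimated correlation). Tyms, the thymidylate synthase that 5FU inhibits, had a log2 fold change of 2.46 ± 0.15 and Birc5 of 2.26 ± 0.15. For the HSC stem cell genes, 0 of 34 members were higher and 24 lower (0 and 26 adjusted over the list alone, median log2 fold change -0.90, camera adjusted p = 1.3e-25, adjusted p = 8.4e-07 at an estimated correlation). Of the quiescence regulators, 1 of 19 members was higher and 10 lower (1 and 11 adjusted over the list alone, median log2 fold change -0.47, camera adjusted p = 5.8e-06, adjusted p = 0.021 at an estimated correlation). These included Cdkn1c (-1.95 ± 0.19), which encodes the cell cycle inhibitor p57, and Hes1 (-2.18 ± 0.20). The list of immediate early and dissociation genes, which can respond to cell handling, was lower too: 1 of 21 members was higher and 14 lower (1 and 17 adjusted over the list alone, median log2 fold change -0.88, camera adjusted p = 1.6e-15, adjusted p = 0.011 at an estimated correlation). Klf2 had a log2 fold change of -2.15 ± 0.14 and Fos of -1.33 ± 0.09. Egr1 (-2.03 ± 0.14) belongs to both of these lists. For interferon response genes, 1 of 32 members was higher and 12 lower (1 and 15 adjusted over the list alone, median log2 fold change -0.48, camera adjusted p = 6.6e-06, adjusted p = 0.10 at an estimated correlation). Gbp6 had a log2 fold change of -1.89 ± 0.23. Niche receptor genes were lower as well: 3 of 45 members were higher and 9 lower (4 and 12 adjusted over the list alone, median log2 fold change -0.22, camera adjusted p = 0.023, adjusted p = 0.045 at an estimated correlation). Among markers of other cell types, endothelial genes had 1 higher and 4 lower of 18 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0075, adjusted p = 0.027 at an estimated correlation). Megakaryocyte genes had 1 higher and 5 lower of 20 (1 and 6 adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.064 at an estimated correlation). HSC niche ligands had 0 higher and 9 lower of 38 (0 and 10 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.10 at an estimated correlation).

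In all, limma called 2060 of 16171 genes, 1055 higher and 1005 lower, of which 356 and 496 had a log2 fold change of at least 1 in size. Each alternative setting and each omitted library left the total within 1.5 times, between 1472 and 2042 for omitted libraries. The balance turned with no filter (922 higher and 930 lower) and without Reserve replicate 1 (964 higher and 987 lower) or 2 (981 higher and 1061 lower), and a mean FPKM of at least 5 left 951 higher and 555 lower.

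Among homeostatic HSPC groups, MPP differed most from Reserve by the number of called genes. Dntt was at 280.3 ± 31.9 FPKM (SD, n = 4) in MPP and 0.550 ± 0.963 FPKM (SD, n = 4) in Reserve (log2 fold change 7.66 ± 0.28), and Flt3 was higher (2.70 ± 0.16). Mllt3 was at 10.5 ± 3.46 FPKM (SD, n = 4) in MPP, and Vwf was lower (-4.57 ± 0.23). Kit was also lower, at 60.6 ± 1.64 FPKM (SD, n = 4), a log2 fold change of -0.84 ± 0.07. Nupr1, a stress-induced nuclear protein gene, was lower (-5.11 ± 0.30, adjusted p = 9.9e-09).

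For HSC stem cell genes, 0 of 34 members were higher and 33 lower (0 and 33 adjusted over the list alone, median log2 fold change -2.19, camera adjusted p = 6.7e-24, adjusted p = 1.2e-06 at an estimated correlation). Every tested cell cycle gene was higher (37 of 37, and 37 adjusted over the list alone), with a camera adjusted p of 1.7e-36 and an adjusted p = 9.0e-04 at an estimated correlation. Lymphoid progenitor genes were raised: 13 of 18 members were higher and 1 lower (14 and 1 adjusted over the list alone, median log2 fold change 1.34, camera adjusted p = 3.2e-09, adjusted p = 0.0028 at an estimated correlation). These included Satb1 (2.64 ± 0.21), a chromatin organizer. Myeloid progenitor genes pointed the same way: 9 of 19 members were higher and 1 lower (9 and 1 adjusted over the list alone, median log2 fold change 0.56, camera adjusted p = 2.1e-05, adjusted p = 0.078 at an estimated correlation). These included Cd48 (4.51 ± 0.21). Megakaryocyte genes were lower: 0 of 20 members were higher and 17 lower (0 and 17 adjusted over the list alone, median log2 fold change -1.62, camera adjusted p = 2.5e-08, adjusted p = 4.0e-04 at an estimated correlation). In the interferon response list, 1 of 32 members was higher and 23 lower (1 and 23 adjusted over the list alone, median log2 fold change -1.02, camera adjusted p = 2.9e-06, adjusted p = 0.078 at an estimated correlation). These included Igtp (-2.20 ± 0.15). Of T and NK cell markers, 2 of 12 were higher, 1 lower and 9 not called (2 and 1 adjusted over the list alone, median log2 fold change 0.29, camera adjusted p = 0.014, adjusted p = 0.078 at an estimated correlation). Lck had a log2 fold change of 1.81 ± 0.14. Among HSC niche ligands, 3 of 38 members were higher and 19 lower (3 and 20 adjusted over the list alone, median log2 fold change -0.69, camera adjusted p = 0.0045, adjusted p = 0.078 at an estimated correlation). The immediate early and dissociation list, which can follow cell handling, was lower: 1 of 21 members was higher and 13 lower (1 and 14 adjusted over the list alone, median log2 fold change -0.84, camera adjusted p = 7.5e-04, adjusted p = 0.18 at an estimated correlation). Endothelial genes had 4 higher and 10 lower of 18 (4 and 10 adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.078 at an estimated correlation). Quiescence regulators had 3 higher and 12 lower of 19 (3 and 13 adjusted over the list alone, camera adjusted p = 0.0058, adjusted p = 0.094 at an estimated correlation). Inflammatory and acute response ligands had 5 higher and 1 lower of 15 (5 and 1 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.060 at an estimated correlation).

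By limma, 6626 of 16171 genes were called, 2056 higher and 4570 lower, 847 and 1962 of them with a log2 fold change of at least 1 in size, and with a median log2 fold change of -0.20 over all tested genes. After median-of-ratios scaling that median was -0.01 and the split was 3120 higher and 3178 lower, while the median of each list named above for MPP kept its sign. Higher and lower calls were then close to equal in number.

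Reserve-gate cells on day 3 after 5FU were set against reserve cells in homeostasis. Kit fell from 109 ± 2.56 FPKM (SD, n = 4) to 30.6 ± 1.82 FPKM (SD, n = 3), a log2 fold change of -1.81 ± 0.07, and the stem cell transcription factor gene Hlf from 112 ± 1.95 FPKM (SD, n = 4) to 20.7 ± 3.25 FPKM (SD, n = 3), a change of -2.39 ± 0.09. Cdkn1a, the p53 target that encodes p21, rose to 33.8 ± 3.41 FPKM (SD, n = 3), a change of 2.36 ± 0.28. Ly6a, which encodes Sca-1, rose (1.21 ± 0.16), and Cxcr4, the receptor of Cxcl12, rose to 25.1 ± 2.85 FPKM (SD, n = 3), a change of 2.33 ± 0.18. The granule genes Mpo (-5.10 ± 0.77) and Elane (-7.49 ± 1.30) fell, while neutrophil genes had 7 higher and 3 lower of 16 (9 and 4 adjusted over the list alone, camera adjusted p = 0.46) and myeloid progenitor genes 10 higher and 6 lower of 19 (11 and 6 adjusted over the list alone, camera adjusted p = 0.17).

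Transcripts of mature lymphocytes appeared at high level. Cd79a, part of the B cell receptor, was at 497 ± 17.3 FPKM (SD, n = 3) against 0.292 ± 0.339 FPKM (SD, n = 4), and Cd3g, part of the T cell receptor complex, was at 113 ± 25.4 FPKM (SD, n = 3) and listed at 0 in each Reserve library, as was Cd3e, at 32.1 ± 3.45 FPKM (SD, n = 3) after 5FU. Igkc, an immunoglobulin gene chosen after its values were seen, was at 0, 1.84, 2283 and 2341 FPKM in Reserve replicates 1 to 4 and at 67127 ± 2162 FPKM (SD, n = 3) after 5FU. For B cell genes, 10 of 11 members were up and 0 down (10 and 0 adjusted over the list alone, median log2 fold change 4.87, camera adjusted p = 8.0e-09, adjusted p = 5.1e-04 at an estimated correlation). Ms4a1 had a log2 fold change of 6.38 ± 0.13. Of T and NK cell genes, 11 of 12 members were up and 0 down (12 and 0 adjusted over the list alone, median log2 fold change 2.85, camera adjusted p = 1.7e-10, adjusted p = 5.1e-04 at an estimated correlation). Macrophage genes moved with them: 11 of 15 members were up and 1 down (11 and 1 adjusted over the list alone, median log2 fold change 1.92, camera adjusted p = 0.0020, adjusted p = 0.023 at an estimated correlation). These included Ctss (2.47 ± 0.13). Endothelial genes went both ways, with 8 higher and 6 lower of 18 (8 and 6 adjusted over the list alone, camera adjusted p = 0.23), and the sinusoidal gene Stab2 stood at 29.4 ± 3.18 FPKM (SD, n = 3), a log2 fold change of 4.85 ± 0.17.

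With these markers raised, the other groups read as follows. Cell cycle genes rose: 36 of 37 members were up and 0 down (36 and 0 adjusted over the list alone, median log2 fold change 2.50, camera adjusted p = 1.3e-19, adjusted p = 0.0088 at an estimated correlation). Birc5 had a log2 fold change of 3.21 ± 0.15 and Rrm2, a ribonucleotide reductase subunit, of 3.58 ± 0.20. HSC stem cell genes fell: 1 of 34 members was up and 25 down (1 and 26 adjusted over the list alone, median log2 fold change -1.07, camera adjusted p = 6.3e-10, adjusted p = 1.7e-04 at an estimated correlation). Lymphoid progenitor genes rose: 11 of 18 members were up and 2 down (11 and 2 adjusted over the list alone, median log2 fold change 1.31, camera adjusted p = 3.4e-04, adjusted p = 0.036 at an estimated correlation). Il7r had a log2 fold change of 4.06 ± 0.26. Adipocyte lineage genes, several of which endothelial cells and macrophages also express, rose: 8 of 12 members were up and 0 down (8 and 0 adjusted over the list alone, median log2 fold change 1.47, camera adjusted p = 0.0022, adjusted p = 0.024 at an estimated correlation). Fabp4 had a log2 fold change of 5.97 ± 0.36 and Cd36 of 2.95 ± 0.21. Of p53 target genes, 10 of 25 members were up and 3 down (10 and 4 adjusted over the list alone, median log2 fold change 0.30, camera adjusted p = 0.17). Bax, a pore-forming apoptosis gene, had a log2 fold change of 1.65 ± 0.09. Inflammatory and acute response ligands included Il1b (4.45 ± 0.51): 9 of 15 members were up and 2 down (10 and 2 adjusted over the list alone, median log2 fold change 1.18, camera adjusted p = 0.020, adjusted p = 0.040 at an estimated correlation). Among drug transport and fluoropyrimidine metabolism genes, 9 of 21 members were up and 10 down (10 and 10 adjusted over the list alone, camera adjusted p = 0.50), with a median log2 fold change of -0.30 and a mean of 0.36.

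Over all genes, limma called 7813 of 16171 genes, 4120 higher and 3693 lower, of which 2064 and 1619 had a log2 fold change of at least 1 in size. A mean FPKM of at least 5 left 3175 higher and 2205 lower. Xist was at 5.24 ± 0.752 FPKM (SD, n = 3) in 5FuReserve and 0.986 ± 0.637 FPKM (SD, n = 4) in Reserve, and the Y-linked gene Ddx3y at 11.6 ± 1.46 FPKM (SD, n = 3) and 26.4 ± 5.28 FPKM (SD, n = 4). Xist and Ddx3y, here and in the comparisons below, were chosen after their values were seen.

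**Figure D1:**
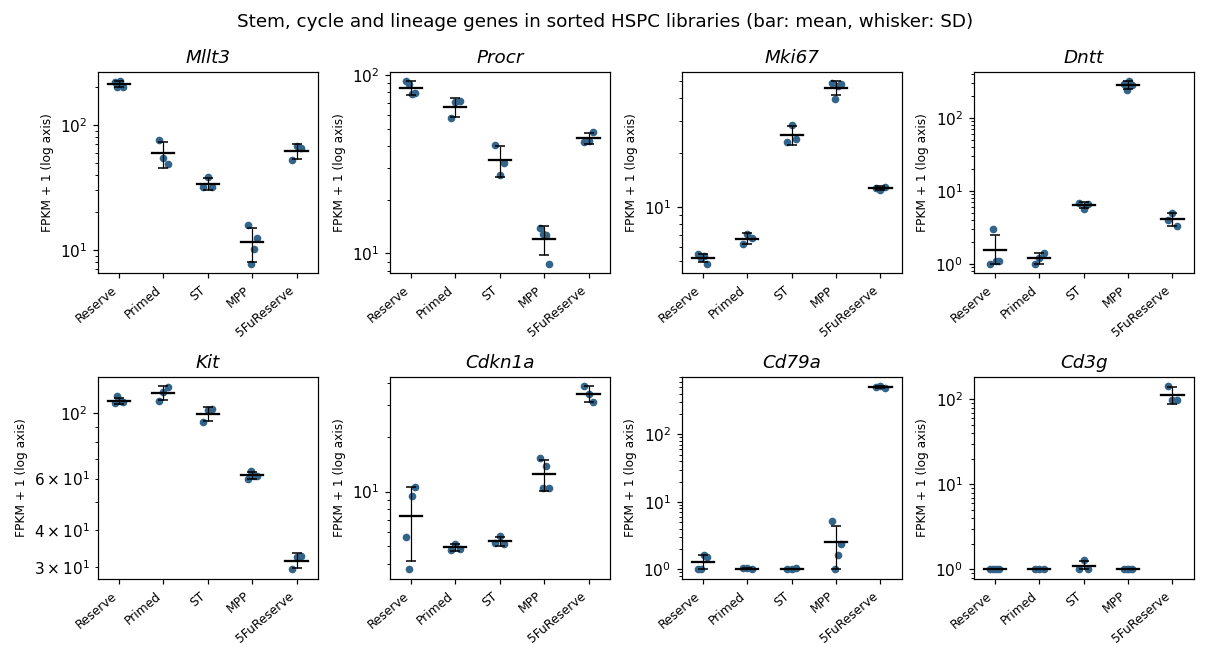
FPKM + 1 on log axes of 8 genes in each HSPC library (points) by group, with the mean (bar) and the SD (whisker, not drawn below 0 FPKM). Mllt3 was highest in Reserve (211 FPKM), Dntt in MPP (280.3 FPKM), and Cd79a and Cd3g in 5FuReserve (497 and 113 FPKM).

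Ncad_bone was compared with Ncad_marrow. Cartilage genes stood apart. Prg4, the joint lubricant proteoglycan, was at 6240.3 ± 2185 FPKM (SD, n = 4) in Ncad_bone and 5.97 ± 1.62 FPKM (SD, n = 4) in Ncad_marrow (log2 fold change 9.77 ± 0.28). Chad was at 1816 ± 883 FPKM (SD, n = 4) and Cytl1 at 1978 ± 1324 FPKM (SD, n = 4) in Ncad_bone, and both were listed at 0 in each Ncad_marrow library. Col1a1, the main collagen of bone, was higher in bone (3.63 ± 0.31), while Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367) was at 17350.4 ± 2102 FPKM (SD, n = 4) and 16604 ± 1249 FPKM (SD, n = 4) (adjusted p = 0.97). Cdh2 (adjusted p = 0.34) and Lepr (adjusted p = 0.73) were not called.

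Of chondrocyte genes, 20 of 21 members were higher and 0 lower (20 and 0 adjusted over the list alone, median log2 fold change 3.63, camera adjusted p = 3.8e-41, adjusted p = 5.5e-08 at an estimated correlation). For osteoblast lineage genes, 16 of 26 members were higher and 2 lower (17 and 2 adjusted over the list alone, median log2 fold change 1.04, camera adjusted p = 1.6e-06, adjusted p = 0.11 at an estimated correlation). Postn had a log2 fold change of 4.42 ± 0.40 and Spp1 of 2.51 ± 0.24. Pericyte and smooth muscle genes were higher in bone: 9 of 14 members were higher and 0 lower (9 and 0 adjusted over the list alone, median log2 fold change 1.11, camera adjusted p = 4.7e-08, adjusted p = 0.011 at an estimated correlation). Acta2 had a log2 fold change of 5.05 ± 0.38 and Rgs5 of 3.93 ± 0.34. Schwann cell genes were too: 9 of 13 members were higher and 0 lower (10 and 0 adjusted over the list alone, median log2 fold change 0.96, camera adjusted p = 3.5e-05, adjusted p = 0.0031 at an estimated correlation). Mbp had a log2 fold change of 1.94 ± 0.25. WNT pathway antagonists, secreted inhibitors, gave 8 higher and 1 lower of 11 (8 and 1 adjusted over the list alone, camera adjusted p = 1.6e-04, adjusted p = 0.027 at an estimated correlation). Notum had a log2 fold change of 2.73 ± 0.26. In the stromal progenitor list, 11 of 24 members were higher and 3 lower (11 and 3 adjusted over the list alone, median log2 fold change 0.48, camera adjusted p = 0.0017, adjusted p = 0.046 at an estimated correlation). Fibroblast and matrix genes included Aspn (5.85 ± 0.27) and Lum (3.09 ± 0.37): 10 of 19 members were higher and 0 lower (10 and 0 adjusted over the list alone, median log2 fold change 1.02, camera adjusted p = 2.4e-05, adjusted p = 0.068 at an estimated correlation). The interferon response list went the other way: 0 of 32 members were higher and 10 lower (0 and 10 adjusted over the list alone, median log2 fold change -0.55, camera adjusted p = 2.4e-05, adjusted p = 0.14 at an estimated correlation). Bst2 had a log2 fold change of -1.80 ± 0.19 and Mx1 of -1.59 ± 0.26.

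Of the markers of blood cells, neutrophil and erythroid genes were higher in Ncad_bone at the preset correlation alone. For neutrophil genes, 9 of 16 members were higher and 0 lower (10 and 0 adjusted over the list alone, median log2 fold change 1.81, camera adjusted p = 3.8e-04, adjusted p = 0.39 at an estimated correlation). Ltf had a log2 fold change of 4.47 ± 0.73, and the erythroid list had 8 higher and 0 lower of 17 (8 and 0 adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.47 at an estimated correlation). Macrophage genes had 2 higher of 18, B cell genes 0 of 13 and T and NK cell genes 0 of 11, with none lower. Cell cycle genes had 14 higher and 0 lower of 37 (22 and 0 adjusted over the list alone, camera adjusted p = 1.6e-04, adjusted p = 0.47 at an estimated correlation). Niche receptor genes had 21 higher and 2 lower of 51 (21 and 2 adjusted over the list alone, camera adjusted p = 1.9e-04, adjusted p = 0.053 at an estimated correlation). The libraries of Ncad_bone differed among themselves: Col1a1 was at 579, 424, 178 and 159 FPKM, and Mpo at 248 FPKM in replicate 3. Xist was at 15.8 ± 2.64 FPKM (SD, n = 4) in Ncad_marrow and 1.73 ± 0.616 FPKM (SD, n = 4) in Ncad_bone, and Ddx3y at 18.8 ± 2.06 FPKM (SD, n = 4) in Ncad_bone with no Ncad_marrow library above 0.0350 FPKM. In this comparison, limma called 4673 of 18972 genes, 2785 higher and 1888 lower, of which 1285 and 651 had a log2 fold change of at least 1 in size. The count was 2842 of 9753 genes when the mean FPKM had to be at least 5, and the call of Ltf was lost with only these groups fitted (adjusted p = 0.059).

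Both N-cadherin populations together were set against the equal-weight mean of the Col2.3_GFP, Cxcl12_RFP, Lepr, Nestin_GFP and Ng2_RFP cells. Cxcl12 (2.09 ± 0.24) and Lepr (2.11 ± 0.21) were higher in the N-cadherin populations, as were Vcam1 (1.94 ± 0.13), which encodes an adhesion molecule, and Trf, the transferrin gene (2.10 ± 0.13). All 4 genes and Adipoq (2678 FPKM in Ncad_bone, 4099 in Lepr) were lowest in Col2.3_GFP and Ng2_RFP cells. Means of Cxcl12 and Lepr were 14534 and 863 FPKM in Nestin_GFP and 16016 and 812 in Lepr, near Ncad_marrow (16604 and 1014). Cdh2 was not called (-0.01 ± 0.09, adjusted p = 0.94). Cks2, a cell cycle kinase subunit, was lower (-2.51 ± 0.17, adjusted p = 1.2e-13).

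Interferon response genes, with Iigp1 (1.89 ± 0.16) and Bst2 (1.56 ± 0.11), gave 28 higher and 0 lower of 32 (30 and 0 adjusted over the list alone, median log2 fold change 0.92, camera adjusted p = 1.3e-14, adjusted p = 0.033 at an estimated correlation). Population pairs with Col2.3_GFP or Ng2_RFP had 25 to 29 higher, others 4 to 23 with 0 to 9 lower. The HSC niche ligands gave 23 higher and 6 lower of 56 (26 and 6 adjusted over the list alone, camera adjusted p = 3.1e-05, adjusted p = 0.34 at an estimated correlation). These included Bmp6 (1.95 ± 0.11) and Gas6 (2.25 ± 0.19). Adipocyte lineage genes, with Lpl (2.28 ± 0.14) and Adipoq (1.87 ± 0.20), had 7 higher and 2 lower of 15 (also adjusted over the list alone, median log2 fold change 0.20, camera adjusted p = 0.010, adjusted p = 0.34 at an estimated correlation). The cell cycle list was lower: 0 of 37 members were higher and 35 lower (0 and 37 adjusted over the list alone, median log2 fold change -1.30, camera adjusted p = 4.8e-22, adjusted p = 0.078 at an estimated correlation). Pcna had a log2 fold change of -1.10 ± 0.09. Osteoblast lineage genes were lower too: 2 of 26 members were higher and 11 lower (2 and 11 adjusted over the list alone, median log2 fold change -0.34, camera adjusted p = 0.010, adjusted p = 0.51 at an estimated correlation). Mepe had a log2 fold change of -1.61 ± 0.13. Neutrophil genes were lower alongside: 0 of 16 members were higher and 12 lower (0 and 13 adjusted over the list alone, median log2 fold change -2.14, camera adjusted p = 5.7e-05, adjusted p = 0.38 at an estimated correlation). Camp had a log2 fold change of -2.85 ± 0.47, and the macrophage list had 2 higher and 4 lower of 18 (2 and 4 adjusted over the list alone, camera adjusted p = 0.53). Erythroid genes had 0 higher and 10 lower of 17 (0 and 10 adjusted over the list alone, camera adjusted p = 6.3e-05, adjusted p = 0.38 at an estimated correlation). The B cell list had 1 higher and 7 lower of 13 (2 and 8 adjusted over the list alone, camera adjusted p = 0.097), and T and NK cell genes had 0 higher and 2 lower of 11. Niche receptor genes had 19 higher and 8 lower of 51 (19 and 8 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.38 at an estimated correlation). Endothelial genes had 1 higher and 10 lower of 21 (1 and 10 adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.68 at an estimated correlation). Schwann cell genes had 1 higher and 7 lower of 13 (1 and 8 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.23 at an estimated correlation).

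For this contrast, limma called 7957 of 18972 genes, 4070 higher and 3887 lower, of which 640 and 652 had a log2 fold change of at least 1 in size. With a mean FPKM of at least 5 required, 4922 of 9753 genes were called. The balance turned with a pseudocount of 0.1 (3782 higher and 3954 lower), after median-of-ratios scaling (3716 higher and 4177 lower) and with only the compared groups fitted (4296 higher and 4357 lower).

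Ncad_bone cells were compared with Col2.3_GFP cells, the osteoblast reporter population. Lepr (5.07 ± 0.35), Cxcl12 (4.22 ± 0.41) and Vcam1 (4.89 ± 0.22) were higher in Ncad_bone, as was Cdh2 (1.06 ± 0.15). Col1a1 was lower (-1.63 ± 0.31), as were Bglap3 (-3.88 ± 0.25) and Mepe (-3.42 ± 0.22), genes of mineralized matrix. The muscle genes Tnnt3 (-8.26 ± 0.34), Myl1 (-7.94 ± 0.30) and Pvalb (-8.09 ± 0.19) were among those with the lowest fold change, and Tnnt3 stood at 659.9 ± 130.3 FPKM (SD, n = 4) in Col2.3_GFP cells and 1.77 ± 2.40 FPKM (SD, n = 4) in Ncad_bone.

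In the osteoblast lineage list, 2 of 26 members were higher and 16 lower (2 and 16 adjusted over the list alone, median log2 fold change -1.15, camera adjusted p = 1.7e-04, adjusted p = 0.24 at an estimated correlation). Chondrocyte genes went both ways: 6 of 21 members were higher and 14 lower (6 and 14 adjusted over the list alone, median log2 fold change -2.16, camera adjusted p = 1.7e-04, adjusted p = 0.071 at an estimated correlation). Matn1 had a log2 fold change of -5.09 ± 0.17 and Cytl1 of 7.04 ± 0.37. Among HSC niche ligands, 31 of 56 members were higher and 8 lower (32 and 9 adjusted over the list alone, median log2 fold change 0.69, camera adjusted p = 6.5e-07, adjusted p = 0.098 at an estimated correlation). These included Bmp6 (4.44 ± 0.19) and Il34 (5.28 ± 0.28). Of the niche receptor genes, 29 of 51 members were higher and 8 lower (30 and 8 adjusted over the list alone, median log2 fold change 0.66, camera adjusted p = 2.5e-05, adjusted p = 0.053 at an estimated correlation). Inflammatory and acute response ligands were raised: 13 of 21 members were higher and 1 lower (13 and 1 adjusted over the list alone, median log2 fold change 1.74, camera adjusted p = 2.1e-04, adjusted p = 0.053 at an estimated correlation). Csf1 had a log2 fold change of 3.69 ± 0.23. For the interferon response list, 25 of 32 members were higher and 0 lower (25 and 0 adjusted over the list alone, median log2 fold change 1.75, camera adjusted p = 8.0e-12, adjusted p = 0.053 at an estimated correlation). The immediate early and dissociation list, which can follow cell handling, had 14 higher and 4 lower of 23 (14 and 4 adjusted over the list alone, camera adjusted p = 4.1e-04, adjusted p = 0.35 at an estimated correlation). Socs3 had a log2 fold change of 3.59 ± 0.30. Every tested cell cycle gene was lower in Ncad_bone (37 of 37, also adjusted over the list alone, median log2 fold change -2.76, camera adjusted p = 1.2e-20, adjusted p = 0.053 at an estimated correlation). Erythroid genes, markers of cells excluded by the Ter119 gate, were lower: 1 of 17 members was higher and 11 lower (1 and 11 adjusted over the list alone, median log2 fold change -2.32, camera adjusted p = 6.0e-04, adjusted p = 0.37 at an estimated correlation). The endothelial list had 0 higher and 17 lower of 21 (0 and 17 adjusted over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.35 at an estimated correlation). The B cell list had 1 higher and 8 lower of 13 (2 and 8 adjusted over the list alone, camera adjusted p = 0.082), with a median log2 fold change of -2.37. Col2.3_GFP libraries differed in lymphoid genes, chosen after their values were seen: Cd79a was at 10.8, 41.4, 101 and 11.3 FPKM, and Dntt at 2.86, 19.1, 43.2 and 2.75 FPKM. Quiescence regulators had 10 higher and 3 lower of 19 (10 and 3 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.053 at an estimated correlation). Myeloid progenitor genes had 5 higher and 2 lower of 19 (3 and 1 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.50 at an estimated correlation). Stromal progenitor genes had 11 higher and 6 lower of 24 (11 and 6 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.055 at an estimated correlation). Adipocyte lineage genes had 8 higher and 0 lower of 15 (9 and 1 adjusted over the list alone, camera adjusted p = 1.7e-04, adjusted p = 0.053 at an estimated correlation).

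Here limma called 8571 of 18972 genes, 3889 higher and 4682 lower, of which 2086 and 2655 had a log2 fold change of at least 1 in size. With a mean FPKM of at least 5 required, the count was 5460 of 9753, and no camera call of this comparison held at an estimated correlation.

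Ncad_marrow cells were compared with Lepr+ stromal cells. Lepr was at 1014 ± 320.1 FPKM (SD, n = 4) and 812 ± 137 FPKM (SD, n = 6) (adjusted p = 0.65), and neither this gene nor Cxcl12 (adjusted p = 0.98) was called. Cdh2 was lower in Ncad_marrow (-0.69 ± 0.13), a call lost with a pseudocount of 0.1 (adjusted p = 0.063). Aldh1a2, a retinoic acid-synthesizing enzyme (4.15 ± 0.26), and the growth factor gene Ptn (3.57 ± 0.26) were higher in Ncad_marrow, and Serpina3n, a protease inhibitor (-4.88 ± 0.28), and Spp1 (-2.15 ± 0.21) were lower. Xist was higher (4.01 ± 0.42) and the Y-linked Eif2s3y lower (-5.18 ± 0.20) in Ncad_marrow.

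For interferon response genes, 23 of 32 members were higher and 0 lower (27 and 0 adjusted over the list alone, median log2 fold change 0.83, camera adjusted p = 1.9e-18, adjusted p = 0.0047 at an estimated correlation). Bst2 had a log2 fold change of 2.68 ± 0.18. Cell cycle genes were lower: 0 of 37 members were higher and 29 lower (0 and 33 adjusted over the list alone, median log2 fold change -1.26, camera adjusted p = 2.9e-26, adjusted p = 0.025 at an estimated correlation). Mki67 had a log2 fold change of -1.70 ± 0.21. The quiescence regulators were lower as well: 2 of 19 members were higher and 7 lower (2 and 7 adjusted over the list alone, median log2 fold change -0.23, camera adjusted p = 9.8e-05, adjusted p = 0.0019 at an estimated correlation). Btg2 had a log2 fold change of -1.29 ± 0.15 and Cdkn1a of -1.80 ± 0.22. The immediate early and dissociation list, which can follow cell handling and also holds Btg2, moved with it: 1 of 23 members was higher and 11 lower (1 and 12 adjusted over the list alone, median log2 fold change -0.49, camera adjusted p = 5.9e-10, adjusted p = 0.083 at an estimated correlation). Osteoblast lineage genes gave 7 higher and 2 lower of 26 (9 and 2 adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.52 at an estimated correlation). Neutrophil markers moved with these groups: 0 of 16 members were higher and 12 lower (0 and 15 adjusted over the list alone, median log2 fold change -3.53, camera adjusted p = 4.7e-16, adjusted p = 0.027 at an estimated correlation), with Fcnb at 82.6 ± 45.5 FPKM (SD, n = 6) in Lepr+ cells and 0.994 ± 0.789 FPKM (SD, n = 4) in Ncad_marrow. The myeloid progenitor list had 0 higher and 8 lower of 19 (0 and 10 adjusted over the list alone, camera adjusted p = 4.5e-06, adjusted p = 0.19 at an estimated correlation), and the erythroid list 0 higher and 11 lower of 17 (0 and 14 adjusted over the list alone, camera adjusted p = 8.1e-11, adjusted p = 0.083 at an estimated correlation). Endothelial genes had 0 higher and 4 lower of 21 (0 and 4 adjusted over the list alone, camera adjusted p = 3.6e-04, adjusted p = 0.41 at an estimated correlation). Megakaryocyte genes had 0 higher and 4 lower of 21 (0 and 4 adjusted over the list alone, camera adjusted p = 0.0020, adjusted p = 0.53 at an estimated correlation). Macrophage genes had 0 higher and 3 lower of 18 (0 and 3 adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.52 at an estimated correlation). Pf4 was at 2981 FPKM in Lepr replicate 3 and at most 39.6 FPKM in the other Lepr libraries. Over all genes, limma called 2395 of 18972 genes, 1267 higher and 1128 lower, of which 348 and 557 had a log2 fold change of at least 1 in size, and without Lepr replicate 3 the number was 2103. The balance turned with a pseudocount of 0.1 (975 higher and 1220 lower), after median-of-ratios scaling (1041 higher and 1324 lower) and with a mean FPKM of at least 5 (798 higher and 825 lower). Inflammatory and acute response ligands had 1 higher and 8 lower of 21 (3 and 10 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.088 at an estimated correlation).

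**Figure D2:**
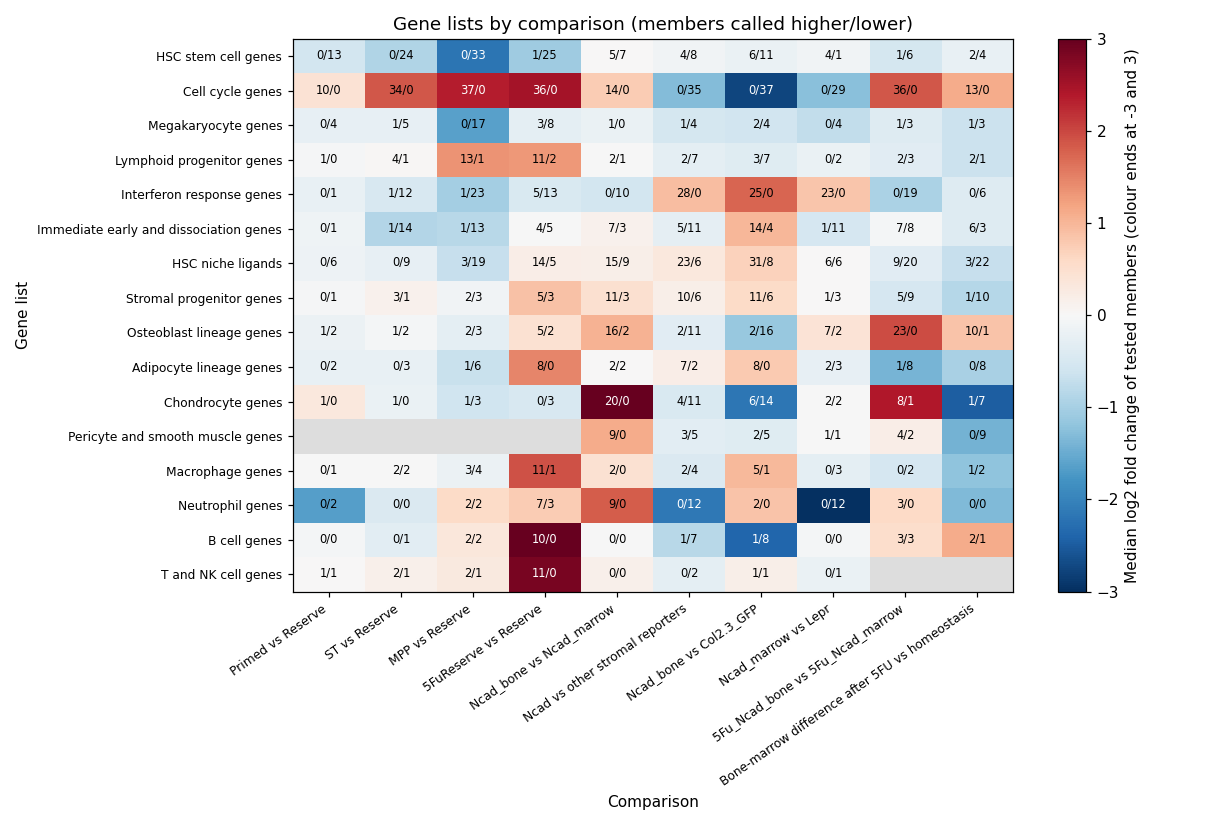
Median log2 fold change of the tested members of 16 gene lists (colour, ends at -3 and 3) in each of the 10 comparisons, with the numbers of members called higher and lower in each cell. Grey cells had under 5 tested members. Cell cycle genes were higher in MPP (37 of 37) and lower in Ncad_bone against Col2.3_GFP cells (37 of 37).

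Secreted and surface ligands that can act on stem cells were compared over the 10 niche populations. Cxcl12 was highest in Ncad_bone, at 17350.4 ± 2102 FPKM (SD, n = 4), with Ncad_marrow at 16604 ± 1249 FPKM (SD, n = 4) and Lepr at 16016 ± 2005 FPKM (SD, n = 6), gaps smaller than the SDs. It was at 6504 ± 355 FPKM (SD, n = 4) in the Cxcl12 reporter cells. Kitl, the ligand of Kit, was highest in Lepr, at 301 ± 27.7 FPKM (SD, n = 6), and was at 251 ± 42.6 FPKM (SD, n = 4) in Ncad_bone. Vcam1 was highest in Ncad_bone, at 901 ± 33.4 FPKM (SD, n = 4), and was at 719.7 ± 169 FPKM (SD, n = 4) in Ncad_marrow. Angpt1, the ligand of the Tek receptor, was highest in Lepr, at 52.1 ± 9.48 FPKM (SD, n = 6), and the bone matrix gene Spp1 in Ng2_RFP, at 19629.6 ± 1011 FPKM (SD, n = 4). Il7 was highest in Cxcl12_RFP, at 127 ± 12.0 FPKM (SD, n = 4), with Ncad_marrow at 115 ± 14.6 FPKM (SD, n = 4), a gap smaller than the SD of Ncad_marrow and larger than that of Cxcl12_RFP.

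Of 16 ligands named beforehand, 15 passed the filter and Wnt10b did not. All 15 differed among the 10 populations by limma's moderated F test (adjusted p at most 2.7e-04), and 3 (Cxcl12, Vcam1 and Tgfb1) had their highest mean in an N-cadherin population. This number was 2 with geometric means and 1 after median-of-ratios scaling, where Cxcl12 was highest in Lepr and Tgfb1 in MK, so the leading population of those 2 genes was not settled. Over all 56 tested ligands, 8 were highest in Ncad_bone, 6 in Ncad_marrow and 10 in Col2.3_GFP. Kit and Cxcr4, receptors of Kitl and Cxcl12, were at 109 ± 2.56 FPKM (SD, n = 4) and 4.19 ± 0.432 FPKM (SD, n = 4) in Reserve, levels from a separately made table that were not tested against the niche levels.

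**Figure D3:**
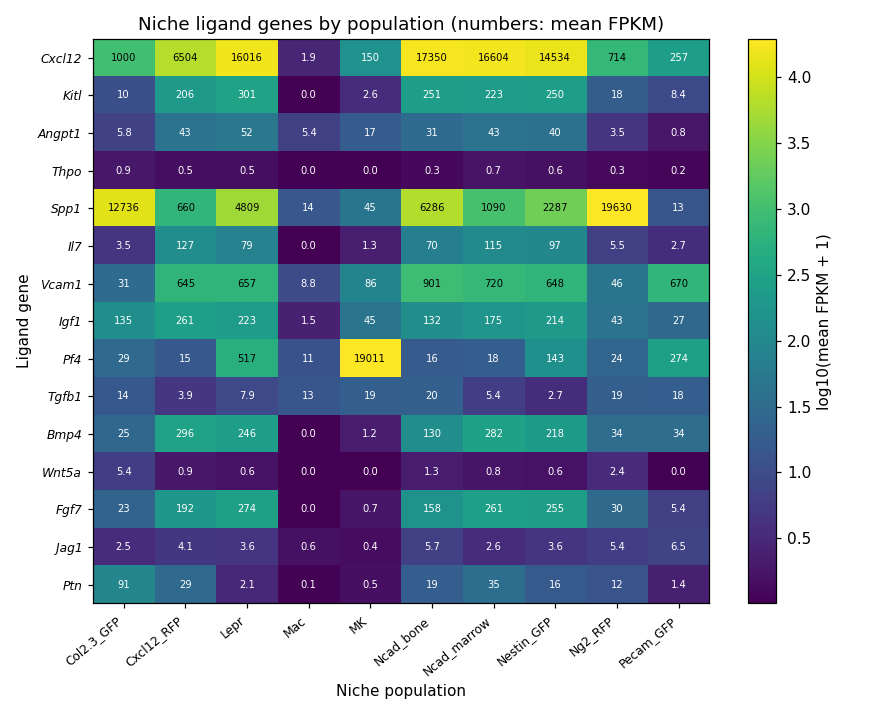
Mean FPKM (numbers) and log10(mean FPKM + 1) (colour) of the 15 tested ligand genes named beforehand in the 10 niche populations. Cxcl12 was at least 14534 FPKM in Lepr, both N-cadherin populations and Nestin_GFP cells.

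After 5FU, bone and marrow N-cadherin reporter cells were compared within their own table. Col1a1 was at 1253 ± 235 FPKM (SD, n = 3) in bone and 79.3 ± 27.6 FPKM (SD, n = 3) in marrow (adjusted p = 2.3e-04). Cxcl12 was at 3501 ± 132 FPKM (SD, n = 3) and 12158 ± 1667 FPKM (SD, n = 3), a log2 fold change of -1.79 ± 0.13, and Lepr was lower in bone as well (-1.18 ± 0.19). Thbs4, a matrix glycoprotein, was higher in bone (6.56 ± 0.17). Adipoq, which encodes adiponectin, was lower (-2.18 ± 0.09). Cdh2 was higher by 0.51 ± 0.15 (adjusted p = 0.047), a call lost without any 1 of the 6 libraries (adjusted p from 0.058 to 0.12) and with no filter (adjusted p = 0.080).

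Osteoblast lineage genes were higher in bone: 23 of 26 members were higher and 0 lower (24 and 1 adjusted over the list alone, median log2 fold change 1.97, camera adjusted p = 2.4e-14, adjusted p = 0.21 at an estimated correlation). Dmp1 had a log2 fold change of 3.44 ± 0.21 and Omd of 3.55 ± 0.16. So were cell cycle genes: 36 of 37 members were higher and 0 lower (36 and 0 adjusted over the list alone, median log2 fold change 1.86, camera adjusted p = 1.3e-19, adjusted p = 0.11 at an estimated correlation). Cdk1 had a log2 fold change of 2.61 ± 0.12 and Ccnb1 of 2.98 ± 0.17. Of chondrocyte genes, 8 of 10 members were higher and 1 lower (8 and 1 adjusted over the list alone, median log2 fold change 2.40, camera adjusted p = 2.2e-05, adjusted p = 0.11 at an estimated correlation). Comp had a log2 fold change of 3.26 ± 0.19. In homeostasis 21 chondrocyte genes were tested, so those failing the filter here drop out. Adipocyte lineage genes were lower: 1 of 14 members was higher and 8 lower (1 and 10 adjusted over the list alone, median log2 fold change -1.38, camera adjusted p = 5.9e-05, adjusted p = 0.21 at an estimated correlation). Lpl had a log2 fold change of -2.01 ± 0.11. For HSC niche ligands, 9 of 49 members were higher and 20 lower (12 and 21 adjusted over the list alone, median log2 fold change -0.34, camera adjusted p = 0.0015, adjusted p = 0.32 at an estimated correlation). Vegfc had a log2 fold change of -1.87 ± 0.09 and Fn1 of 2.90 ± 0.15. Interferon response genes were lower in bone: 0 of 30 members were higher and 19 lower (0 and 21 adjusted over the list alone, median log2 fold change -0.94, camera adjusted p = 5.8e-09, adjusted p = 0.11 at an estimated correlation). Zbp1 had a log2 fold change of -1.78 ± 0.14. B cell genes went both ways, with Ighm lower (-5.53 ± 0.29) and Vpreb3 higher (2.86 ± 0.29): 3 of 10 members were higher and 3 lower (3 and 3 adjusted over the list alone, median log2 fold change 0.54, camera adjusted p = 0.59). The heat shock genes Hspa1a (3.94 ± 0.14) and Hspa1b (4.14 ± 0.16), near-identical copies, were higher in bone. They lead the immediate early and dissociation list, in which 7 of 23 members were higher and 8 lower (7 and 9 adjusted over the list alone, camera adjusted p = 0.69), with a median log2 fold change of -0.07 and a mean of 0.23. Fibroblast and matrix genes had 8 higher and 3 lower of 16 (8 and 3 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.23 at an estimated correlation).

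With 3 libraries a side, limma called 3150 of 13738 genes, 1717 higher and 1433 lower, of which 1004 and 581 had a log2 fold change of at least 1 in size. The count was 1983 without bone replicate 2, 2060 without marrow replicate 3 and 2032 of 9039 with a mean FPKM of at least 5, where the balance turned (961 higher and 1071 lower). No camera call held at an estimated correlation.

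An interaction tested genes of both tables for a change in the bone-marrow difference after 5FU. It cancels only table offsets shared by bone and marrow, so sex, cartilage and 5FU are not told apart. The bone-marrow difference of Cxcl12 was lower after 5FU than in homeostasis, by a log2 value of -1.85 ± 0.19 (adjusted p = 3.4e-05), and so was that of Lepr (-1.40 ± 0.32). The value for Prg4 was -7.28 ± 0.37. Chad, listed at 0 in Ncad_marrow, was at 38.9 ± 8.98 FPKM (SD, n = 3) in bone and 0.0827 ± 0.112 FPKM (SD, n = 3) in marrow after 5FU. Ibsp, a bone matrix protein gene, went the other way (4.58 ± 0.40), as did Runx2 (2.06 ± 0.27), the osteoblast transcription factor. Col1a1 (adjusted p = 0.73) and Cdh2 (adjusted p = 0.23) were not called.

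As a list, osteoblast lineage genes showed a larger bone-marrow difference after 5FU: 10 of 26 members were higher and 1 lower (11 and 1 adjusted over the list alone, median log2 fold change 0.85, camera adjusted p = 1.8e-04, adjusted p = 0.28 at an estimated correlation). Cell cycle genes showed the same: 13 of 37 members were higher and 0 lower (17 and 0 adjusted over the list alone, median log2 fold change 1.12, camera adjusted p = 6.6e-07, adjusted p = 0.28 at an estimated correlation). Kif20a had a log2 difference of 2.04 ± 0.31. For adipocyte lineage genes, 0 of 13 members were higher and 8 lower (0 and 8 adjusted over the list alone, median log2 fold change -0.98, camera adjusted p = 3.0e-05, adjusted p = 0.015 at an estimated correlation). Fabp4 had a log2 difference of -2.70 ± 0.30 and Cebpa of -2.54 ± 0.29. The HSC niche ligands gave 3 higher and 22 lower of 49 (4 and 24 adjusted over the list alone, camera adjusted p = 6.5e-06, adjusted p = 0.015 at an estimated correlation). Il34 had a log2 difference of -2.79 ± 0.19 and Cxcl14 of -2.69 ± 0.20. Stromal progenitor genes were lower: 1 of 20 members was higher and 10 lower (1 and 11 adjusted over the list alone, median log2 fold change -0.85, camera adjusted p = 0.0011, adjusted p = 0.023 at an estimated correlation). Acta2 had a log2 difference of -4.32 ± 0.47 and Nt5e of -4.67 ± 0.48. Pericyte and smooth muscle genes followed: 0 of 11 members were higher and 9 lower (0 and 9 adjusted over the list alone, median log2 fold change -1.42, camera adjusted p = 1.5e-04, adjusted p = 0.26 at an estimated correlation). Of chondrocyte genes, 1 of 10 members was higher and 7 lower (1 and 7 adjusted over the list alone, median log2 fold change -2.48, camera adjusted p = 0.0023, adjusted p = 0.28 at an estimated correlation). Sex-linked genes differed between the tables: both groups after 5FU listed Ddx3y, at 20.9 ± 3.82 FPKM (SD, n = 3) in bone and 19.8 ± 0.774 FPKM (SD, n = 3) in marrow, while Ncad_marrow in homeostasis had Xist at 15.8 ± 2.64 FPKM (SD, n = 4). Niche receptor genes had 4 higher and 17 lower of 39 (4 and 21 adjusted over the list alone, camera adjusted p = 3.0e-05, adjusted p = 0.14 at an estimated correlation).

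For the interaction, limma called 2731 of 13316 genes, 1178 higher and 1553 lower, of which 888 and 1108 had a log2 fold change of at least 1 in size. With a mean FPKM of at least 5 required, 1748 of 8235 genes were called. The balance turned with no filter (1751 higher and 1414 lower) and after median-of-ratios scaling (1378 higher and 1359 lower). Of 13316 genes tested in both tables, 518 were called higher in bone in both, against 279 for independent lists, and 296 lower in both, against 157. Another 320 were called in opposite directions.

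**Figure D4:**
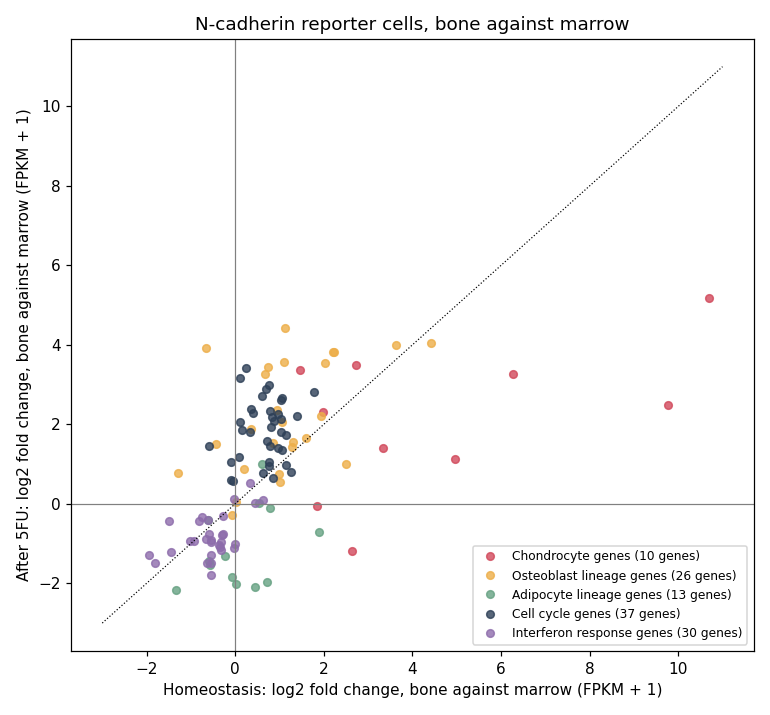
Log2 fold change on FPKM + 1 of bone against marrow N-cadherin reporter cells in homeostasis (x) and after 5FU (y) for members of 5 gene lists tested in both tables, each point a gene, with the line of equal change dotted. Osteoblast lineage and cell cycle genes lay mostly above the line (10 and 13 called higher in the interaction), and chondrocyte and adipocyte lineage genes mostly below it (7 and 8 called lower).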

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

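Tests of the 5FuReserve lymphocyte genes, of the blood cell lists beside the interferon genes, of these genes in Ncad_bone against Ng2_RFP and of the genes called in both bone-marrow comparisons were chosen after the results were seen. Other splits of the libraries into groups of the same sizes tested whether chance labels give as many calls. The real counts and the highest of the other splits were 626 and 170 for Primed against Reserve, 2060 and 614 for ST and 6626 and 18 for MPP. They were 7813 and 3887 for 5FuReserve, 4673 and 1022 for Ncad_bone against Ncad_marrow and 8571 and 3260 for Ncad_bone against Col2.3_GFP. In each, only the real split of 35 reached its count. Chance differences between animals stay open. The same held for 100 drawn splits of Ncad_marrow against Lepr (2395, highest other 993). It held too for the N-cadherin populations against the other stromal reporters (7957, highest other 4077). These mix several differing populations, so that count decides nothing. Bone against marrow after 5FU (3150, highest other 12) allows 10 splits, too few for a share under 0.05. For the interaction, 2 of 100 splits reached the real 2731 genes. The other (4268 genes) swaps bone and marrow after 5FU alone and so adds the differences of both tables. As splits mix bone with marrow, which differ, the count decides nothing.

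In 5FuReserve the median log2 fold change against Reserve was 4.87 for B cell, 2.85 for T and NK cell, 1.92 for macrophage, 0.76 for neutrophil, -0.26 for erythroid and -0.29 for megakaryocyte genes. The gap of 5.16 from lowest to highest argues only against all lists rising alike. A lower share of stem cells stays open, also for the falls of Kit and HSC genes. Other cells in the sort stay open for the rises, those of Ly6a and Cxcr4 among them. With Xist higher and Y-linked genes lower in 5FuReserve, sex was not tested and stays open. B and T cells, or their RNA, among the sorted cells may be the source, since 20 of 22 further B and T cell genes were higher, with Ly6d at 966 ± 112 FPKM (SD, n = 3) in 5FuReserve and 3.64 ± 4.26 FPKM (SD, n = 4) in Reserve, and H2-Ab1 at 1290.0 ± 72.5 FPKM (SD, n = 3) and already 159.8 ± 21.4 FPKM (SD, n = 4). Of these 22, 8 had at least 1 FPKM in Reserve, Lat was not called and Bcl11b not tested, and after a first count Iglc2 and Thy1, whose values had been seen, were left out and the bounds reset. Lineage and c-Kit gates would remove such cells, and expression of these genes by the stem cells themselves was not tested and stays open.

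Xist was higher in Ncad_marrow and Ddx3y in Ncad_bone, so the sex of the mice may lie behind part of the 4673 genes called between them. A test set after Ddx3y was seen in both groups after 5FU asked for 75% of shared calls to point the same way against this. It gave 71.8%, so sex stays open for the comparison as a whole. A test added afterwards counted 814 genes called in the same direction in both tables, against 437 for independent lists, which argues against sex as the whole cause of the shared calls. It speaks for the excess alone, whose genes the count does not single out. Of 3790 genes called in homeostasis, 61.0% kept their sign after 5FU, and folds correlated at r = 0.249. Sex, 5FU and noise are not told apart. Cartilage cells taken along with bone may account for the cartilage genes: 8 of 9 further cartilage genes tested were higher, with Fmod at 348 ± 45.1 FPKM (SD, n = 4) in Ncad_bone and Clec3a at 391 ± 302 FPKM (SD, n = 4), while Col27a1 was lower. The gate would remove cartilage cells without the reporter, and expression of these genes by the reporter cells themselves was not tested and stays open.

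Interferon genes were higher in the N-cadherin populations than in the mean of the other stromal reporters, but Ncad_bone had 4 higher and 9 lower of 32 against Nestin_GFP. All 4 blood cell medians at or below 0 (-2.14 to -0.30) argue only against more blood cells in N-cadherin samples than in that mean. Ncad_bone against Col2.3_GFP, at 0.98 for macrophage, 0.85 for neutrophil and -2.37 for B cell genes, leaves that open. Igkc was at 3.81 to 4812 FPKM in Ncad_bone, so some blood cells may remain. A test of sex, set after Ddx3y was seen in both groups, asked for at least 10 interferon genes called higher in Ncad_bone against Lepr. It gave 14, with 3 lower. It decides nothing, since Xist (1.73 and 0.0357 FPKM) did not overlap. Ncad_marrow, with the most Xist here, had 23 higher and 0 lower against Lepr, as sex predicts. Ncad_bone had 0 and 10 against Ncad_marrow, but also 0 and 19 of 30 after 5FU, with Ddx3y in both. Against Ng2_RFP, with Xist at 4.71 ± 1.15 FPKM (SD, n = 4), Ncad_bone had 26 higher and 0 lower, which argues against sex as the whole cause of that part, and sex stays open for the rest. Mouse line, housing, day of sorting and any biological explanation were not tested and stay open.

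In 8 of 76 group levels printed with at least 4 libraries, 1 library lay far from the others by Dixon's test at the 95% level, which marks about 1 in 20 groups by chance. These were Col1a1 in Col2.3_GFP replicate 3 (719 FPKM, others 958 to 977), Cxcl12 in Ncad_marrow replicate 4 (18474 FPKM, others 15916 to 16101), Dntt in Reserve replicate 2 (1.99 FPKM, others 0.0130 to 0.0990), Itga2 in Reserve replicate 2 (0.707 FPKM, others 0 to 0.0460), Nes in Pecam_GFP replicate 3 (0.682 FPKM, others 1.53 to 1.69), Tnnt3 in Col2.3_GFP replicate 2 (855 FPKM, others 584 to 605), Xist in Cxcl12_RFP replicate 4 (0.746 FPKM, others 0.0200 to 0.0590) and Xist in Lepr replicate 2 (0.177 FPKM, others 0 to 0.0180).

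The interaction marked 2731 genes whose bone-marrow difference differed between homeostasis and 5FU. Among those named, the log2 difference was lower after 5FU for Prg4 (-7.28), Nt5e (-4.67), Acta2 (-4.32), Il34 (-2.79), Fabp4 (-2.70), Cxcl14 (-2.69), Cebpa (-2.54), Cxcl12 (-1.85), Lepr (-1.40), and higher for Ibsp (4.58), Runx2 (2.06), Kif20a (2.04).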

How the results depend on the processing

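Only the fit of protein-coding genes alone was chosen after the data were seen. With a mean FPKM of at least 5 required, which leaves fewer genes to test, called genes numbered 342 (from 626) for Primed against Reserve, 2842 (from 4673) for Ncad_bone against Ncad_marrow, 4922 (from 7957) for the N-cadherin populations against the other stromal reporters, 5460 (from 8571) for Ncad_bone against Col2.3_GFP, 2032 (from 3150) for bone against marrow after 5FU and 1748 (from 2731) for the interaction. Leaving out 1 library at a time gave 215 to 647 for Primed against Reserve, 1472 to 2042 for ST, 5518 to 6603 for MPP and 6752 to 7341 for 5FuReserve. It gave 3680 to 4742 for Ncad_bone against Ncad_marrow, 7102 to 8053 for the N-cadherin populations against the other stromal reporters, 7774 to 8322 for Ncad_bone against Col2.3_GFP, 1666 to 2473 for Ncad_marrow against Lepr, 1983 to 2693 for bone against marrow after 5FU and 2087 to 2990 for the interaction. The count for Primed moved by over 1.5 times without Reserve replicate 3 or 4 or Primed replicate 2 or 3. That for bone against marrow after 5FU did so without bone replicate 2 or marrow replicate 3. Fewer libraries enter these fits. Pseudocount, no filter, scaling, only the compared groups and protein-coding genes alone (counts 83.8% to 108% as large) left each total of called genes within 1.5 times. The balance of higher and lower calls turned with some settings for Primed, ST, the N-cadherin populations against the other stromal reporters, Ncad_marrow against Lepr, bone against marrow after 5FU and the interaction.

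Of 258 list tests, camera called 100 at the preset correlation, 33 with an estimated correlation and 171 with fry, which does not compare a list with other genes. The cause of the fewer calls with an estimated correlation was not tested. The number of named ligands highest in an N-cadherin population was 3, 2 with geometric means and 1 with scaling, and the cause was not tested. For named genes, 2527 values under an alternative stayed on their side of the threshold, 0 changed sign, 1 (Cxcl12 in Primed) gained a call and 13 lost it. The latter were Prss34 and Flt3 in Primed, Ltf in Ncad_bone and Cdh2 in Ncad_marrow and after 5FU, with adjusted p from 0.057 to 0.12.

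Groups share replicate numbers, but deviations of same-numbered libraries correlated at -0.119 to 0.0962, so the numbers were not taken to pair the samples. Between 0 and 2 numbers per comparison correlated best with their own. With the replicate number as a block, called genes numbered 419 for Primed, 1760 for ST, 6565 for MPP, 7502 for 5FuReserve, 4457 for Ncad_bone against Ncad_marrow, 7701 for the N-cadherin populations against the other stromal reporters, 8382 for Ncad_bone against Col2.3_GFP, 1752 for Ncad_marrow against Lepr, 2247 for bone against marrow after 5FU and 2123 for the interaction, each within 1.5 times. The block turned the balance of Ncad_marrow against Lepr (851 higher and 901 lower) and ended the call of Cdh2 after 5FU (adjusted p = 0.065). Genes near 1 FPKM are limited by depth, which differed up to 6.39-fold between niche libraries.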

Other observations

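Values in this part were chosen after they were seen and carry no test. Populations without a comparison of their own differed in lineage transcripts. Ng2_RFP cells held transcripts of bone and cartilage: Bglap, with near-identical copies, was at 21402 ± 2055 FPKM (SD, n = 4) and Col2a1 at 1221 ± 171 FPKM (SD, n = 4). Pecam_GFP cells held the endothelial transcripts Stab2 (705 ± 90.3 FPKM, SD, n = 4) and Emcn (883 ± 246 FPKM, SD, n = 4). In the F4/80+ Mac group, the neutrophil gene S100a8 was at 209472 ± 33039.8 FPKM (SD, n = 4), while C1qa, a complement gene of tissue macrophages, was at 2.09 ± 0.794 FPKM (SD, n = 4), against 98.9 ± 55.9 FPKM (SD, n = 4) in MK.

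The MK libraries lay in pairs. Pf4 was at 29857 and 32765 FPKM in replicates 1 and 2 and at 5582 and 7842 FPKM in replicates 3 and 4. S100a8 was at 50639 and 40620.3 FPKM in the former and 196278 and 175060.0 FPKM in the latter, and Xist at 14.1 and 10.7 against at most 0.462 FPKM. Other niche groups differed in Xist and Ddx3y too. Pecam_GFP had Xist at 25.1 ± 5.58 FPKM (SD, n = 4) and Ddx3y at 0.0323 ± 0.0255 FPKM (SD, n = 4), Lepr had 0.0357 ± 0.0695 FPKM (SD, n = 6) and 21.7 ± 4.65 FPKM (SD, n = 6), and Nestin_GFP had both, at 10.3 ± 2.68 FPKM (SD, n = 4) and 11.6 ± 1.49 FPKM (SD, n = 4). Cxcl12_RFP had little of either, at 0.217 ± 0.353 FPKM (SD, n = 4) and 0.920 ± 0.565 FPKM (SD, n = 4).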
